A study of Rattus norvegicus with 6 samples.

How the data were processed

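Total RNA of 6 samples of transduced INS-1 cells, 3 labelled S487A and 3 labelled S487D, was used to isolate and sequence mRNA. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, which does not mark strand, so reads of overlapping or antisense genes cannot be told apart. Per the submitters' processing notes, bcl2fastq 2.17, cutadapt and TopHat2 2.0.13 were used with the rn6 (Rnor_6.0) build. The read counter, the annotation and any filter are not given in the sources used here.

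The deposited table held RPKM per gene and library for 35362 gene rows, with rn6 position, strand and gene length, per the file headers. Of these, 12182 were at 0 in every library. RPKM times gene length fell on whole multiples of a step in each library, within 0.05 of a read for 100% of values up to 2000 reads and for at least 99.95% of all values. The step matched the sum of the multiples, so the authors' RPKM values are relative to the reads assigned to the listed genes, and reads per gene could be worked out. Totals ran from 9444801 to 10867549 reads per library. A single read in a gene of 1 kb stood for 0.092 to 0.106 RPKM, and the floor of 3 reads for 0.276 to 0.318 RPKM. Gene symbols were used as deposited. Of them, 19187 are current and 2421 older symbols in a RefSeq table of another rat assembly (GRCr8), used for names only. A further 27 gene names had been turned into dates, and 2 names occurred more than once.

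Groups and replicate numbers were taken from sample titles. Library pairs within a group differed by more than counting noise (median chi-square 1.36 to 1.88 times its expectation over 13444 to 13909 genes with at least 20 reads in the pair), so each library was kept as a replicate.

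Genes with RPKM of at least 1 in at least 3 libraries were tested with limma 3.58.1 (R 4.3.3) on log2(RPKM + 1), with empirical Bayes moderation and an intensity trend, the group as the only term, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The values were not scaled further. Men1 was also compared with an exact permutation test. Of 20 gene lists fixed in advance, the 18 with at least 5 tested members were tested with limma camera (preset correlation 0.01, Benjamini-Hochberg over these lists), and again with an estimated correlation; camera sets a list's genes against all other genes. The lists cover islet hormones, beta cell transcription factors, glucose sensing, hormone processing, cAMP and CREB targets, FoxO1 targets, the menin complex, menin targets, cell cycle, ER stress, sterol and fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, interferon response, beta cell disallowed genes, extracellular matrix, neuronal genes, other cells' markers, mitochondrially encoded genes and ribosomal proteins. A few genes belong to more than 1 list.

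Genes named in the text were set by a rule written in advance. It takes 12 genes of interest in any case (Men1, Ins1, Ins2, Iapp, Pdx1, Mafa, Glp1r, Gcg, Foxo1, Creb1, Cdkn1b and Cdkn2c). It adds the 12 largest rises and 12 largest falls among called genes with a proper symbol, mean RPKM of at least 1 in a group and no overlap of the groups. From each list it takes up to 4 called members, those with the smallest p in each direction. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

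The gene and list tests were tested on simulated reads for 12502 genes with the means and depths of these libraries. For S487D against S487A, 22.4% of genes changed by 1.2-fold were recovered, 84% at 1.5-fold, 94% at 2-fold and 98% at 4-fold. Of 163 calls, 9 (5.52%) were false. With fewer calls than the 5564 in the data, the adjusted threshold was stricter, so the recovered shares do not measure recovery in the data. A raised list was found and 0 of 20 unchanged lists were called. The simulated genes were drawn independently of each other. In the data, the lists called had estimated correlations from 0.074 (cell cycle) to 0.644 (ribosomal proteins). The simulation thus does not show how often the list test calls unchanged lists of correlated genes.

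Alternatives set before the data were examined were pseudocounts of 0.1 and 0.01, no filter and a filter at RPKM 5, quantile normalization, median centring, no intensity trend, a replicate block, an estimated list correlation, and each library left out in turn. Chosen after seeing the data were limma voom on the recovered reads, the 10 most read genes of each library and ribosomal RNA left out, and the shifted stretches left out. The design foresaw a count model if the table also held raw counts. The table holds RPKM and not counts, so that model was not used. Matched random lists, shuffled gene orders and splits of the libraries used fixed seeds. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for tables and figures.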

Results

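INS-1 is a rat insulinoma line that secretes insulin and is used as a model of the pancreatic beta cell. Messenger RNA was sequenced from INS-1 cells that overexpressed a Flag-tagged menin mutant delivered by retrovirus. Menin, the product of Men1, is a nuclear scaffold protein that binds MLL histone methyltransferases and other transcriptional regulators. In the S487A mutant the serine is replaced by alanine, which cannot be phosphorylated, and in the S487D mutant by aspartate, an acidic residue often used in place of a phosphorylated serine. The comparison asks how the transcriptome differs between cells carrying the 2 mutants, in a study of menin phosphorylation downstream of GLP-1, an incretin hormone. Each group held 3 libraries. Reads assigned to listed genes, worked out from RPKM and gene length, numbered 10037113, 10867549 and 10283959 in S487A and 10253573, 9523343 and 9444801 in S487D. Ribosomal RNA took 0.93 to 2.49% of them in S487A and 2.15 to 4.50% in S487D. Cells with wild-type menin or without a transgene were not analysed here, so every direction below is S487D relative to S487A. Values are mean RPKM ± SD over n = 3 libraries per group. Folds and log2 changes are on the log2(RPKM + 1) scale, which understates the change of genes near or below 1 RPKM. The labels do not say that libraries of a group came from separate cultures or transductions, so p-values measure the spread between these samples, which may be technical, and the mutant goes together with the cell population that carries it. With 3 libraries against 3, an exact permutation test of a single gene cannot give a two-sided p under 0.1.

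S487D cells had more insulin, glucagon and islet amyloid mRNA, more mRNA of the insulin gene activator Mafa, and far less of the calcium-binding S100 genes S100a3, S100a4 and S100a6, of gastrin and of the GTPase gene Rnd1. Of 12527 genes tested, 5564 (44.4%) changed, 2523 upward and 3041 downward in S487D (limma, Benjamini-Hochberg adjusted p under 0.05). Most changes were small, with 4530 of them under 1.5-fold. At 2-fold or more, 68 genes were higher and 244 lower; the numbers rose to 118 and 417 with a pseudocount of 0.1 in place of 1, and to 127 and 440 with voom on recovered reads. At 4-fold or more, 9 genes were higher and 33 lower. Upward changes made up 45.3% of calls with values as deposited, 55.4% after quantile normalization and 58.9% after centring each library on its median. In 6835 genes (54.6%) the groups' values did not overlap, where chance gives 10%. The first principal component held 78.9% of the variance and separated the groups. Across genes, which are not independent replicates, Pearson's r was 0.995 to 0.996 within groups and 0.974 to 0.977 between them.

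Men1, on chromosome 1 from 221704408 to 221710343 (rn6), was read at 74.3 ± 2.8 RPKM in S487A and 112 ± 7.8 in S487D, a log2 change of 0.58 (SE 0.055, limma adjusted p = 2.89e-05). The libraries held 71.2, 76.7 and 75.0 RPKM in S487A and 113, 103 and 119 in S487D (two-sided exact permutation p = 0.1, the smallest possible). The labels do not give the species of the menin in the construct, so the split of these reads between transgene and rat gene is unknown. The mutated codon was not examined. The 50 tested genes from Men1 to 225087288 had a median log2 change of 0.20, and the 50 from 220727292 to 221693518 had 0.16. Genes around Men1 thus also tended to be higher in S487D, by less than Men1 itself. These windows were picked after the values were seen. The list of menin and MLL complex members did not move as a group. Its MLL methyltransferase genes were not among those tested, so the list says nothing of their level. Of 19 listed genes, 18 were found by symbol, and the untested one of these reached at most 0.0487 RPKM. The list also holds other regulators such as Foxo1 and Creb1. Of 17 tested, 3 rose, 3 fell and 11 passed no test, and the median log2 change was -0.00 (camera adjusted p = 0.88, camera direction up). The median's sign turned in several alternatives, up to 0.05 after median centring. Besides Men1, the arginine methyltransferase gene Prmt5 rose 1.15-fold. Foxo1, a forkhead factor restrained by insulin signalling, fell from 22.1 ± 0.89 to 11 ± 1.4 RPKM and the histone deacetylase gene Hdac2 from 118 ± 5.5 to 81.2 ± 1.3. Both lie in long stretches of lowered genes on chromosomes 2 and 20, described at the end. Creb1, the cAMP-responsive factor, was read at 2.67 ± 0.27 and 2.61 ± 0.13 RPKM (log2 change -0.02, adjusted p = 0.847), with a positive sign after quantile normalization (0.10) or median centring (0.03).

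Islet hormone mRNAs mostly rose, with gastrin as the exception. Ins1, on chromosome 1 from 272799784 to 272800351, rose from 4683 ± 292 to 16700 ± 551 RPKM (log2 change 1.84, SE 0.058, adjusted p = 2.41e-08), and its share of assigned reads was 0.20 to 0.23% in S487A and 0.73 to 0.78% in S487D. Ins2 rose 3.15-fold, from 108 ± 1.4 to 341 ± 15.8 RPKM. Gcg, the proglucagon gene, on chromosome 3 from 48442635 to 48451650, rose from 96.0 ± 6.6 to 819 ± 41 RPKM (log2 change 3.08, SE 0.056, adjusted p = 7.39e-10). Iapp, islet amyloid polypeptide, rose from 237 ± 11 to 473 ± 31 RPKM. Gast, the gastrin gene, went the other way, from 102 ± 5.0 to 8.14 ± 0.56 RPKM (log2 change -3.49, adjusted p = 4.18e-10). Of the 6 hormone genes tested, 4 rose, 1 fell and 1 passed no test (median log2 change 1.32, camera adjusted p = 0.0136). The list's adjusted p = 0.574 with an estimated correlation, 0.215 after quantile normalization and 0.130 with the most read genes left out, within a range of 1.59e-04 to 0.574 over 18 alternatives. Leaving out the most read genes removes Ins1, a risen member of the list, and the list's median log2 change was then 1.02. Quantile normalization sets Ins1 to a log2 change of 0, since it ranks at the top of both groups. Ins1 and Ins2 are near-identical copies whose reads the counting could split unevenly, and the Iapp row overlaps Slco1a5, so single values of these genes are uncertain. Krt7, a keratin of ductal cells, fell alongside (log2 change -1.38).

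**Figure D1:**
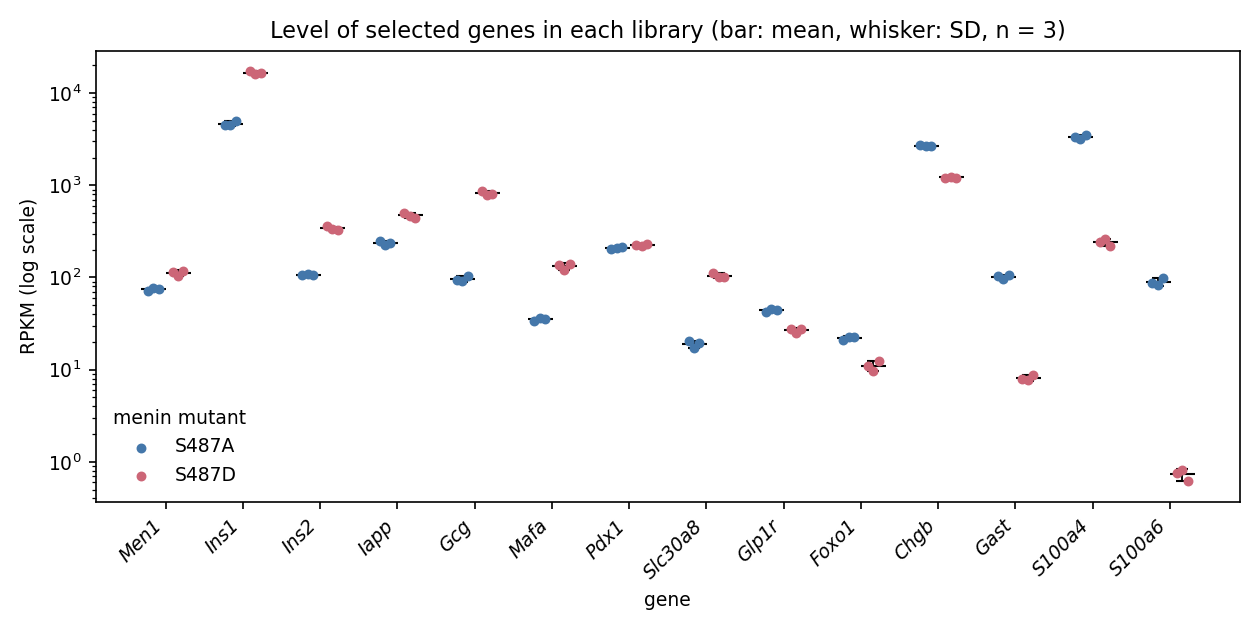
RPKM (log scale) of 14 genes in each library, with S487A in blue and S487D in red; bars are means and whiskers SDs over 3 libraries. Ins1, Ins2, Iapp, Gcg, Mafa and Slc30a8 sit higher in every S487D library, and Glp1r, Foxo1, Chgb, Gast, S100a4 and S100a6 lower.

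Beta cell transcription factors moved in both directions. Mafa, which activates insulin transcription, rose from 35 ± 1.0 to 133 ± 10.7 RPKM (log2 change 1.89, SE 0.059, adjusted p = 2.18e-08). Rfx6, a factor needed for islet cell formation, fell from 58.5 ± 2.4 to 26.7 ± 1.3 RPKM and Rfx3 fell from 13.5 ± 0.33 to 7.59 ± 0.12. Rfx6 lies in the lowered stretch of chromosome 20, and the Rfx3 row overlaps another transcript. Of 18 tested, 5 rose, 11 fell and 2 passed no test (median log2 change -0.26, camera adjusted p = 0.129). The list passed the threshold, downward, without a filter on low values (adjusted p = 0.0499) and after quantile normalization (0.0294), within a range of 0.0294 to 0.730 over 18 alternatives. Pdx1, a master regulator of the pancreas, was near its threshold, at 207 ± 5.7 and 226 ± 6.7 RPKM (log2 change 0.12, adjusted p = 0.0299). Its call was lost when S487A replicate 1 (adjusted p = 0.0800), S487A replicate 2 (0.0671), S487D replicate 1 (0.0659) or S487D replicate 3 (0.109) was left out, and in 4 other alternatives, within a range of 0.00489 to 0.865 over all 17.

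Adjusted over the list alone, counts of risen and fallen genes equalled those adjusted over all genes tested for each list except the granule, cell cycle, glycolysis and ribosomal protein lists, where both are given. Among genes of glucose sensing and incretin reception, Slc30a8, the zinc transporter of insulin granules, rose from 19.0 ± 1.6 to 105 ± 6.3 RPKM (log2 change 2.40, adjusted p = 1.11e-08). Sytl4, a granule-docking protein gene, rose from 17.2 ± 1.3 to 66.7 ± 1.7 RPKM. Glp1r, the GLP-1 receptor gene, fell from 44.0 ± 1.4 to 26.8 ± 1.6 RPKM (log2 change -0.70, adjusted p = 6.39e-06) and Abcc8, the sulfonylurea receptor subunit, fell from 45.1 ± 1.1 to 33.4 ± 1.6, in a run of lowered genes on chromosome 1 described at the end. Of 17 tested, 6 rose, 6 fell and 5 passed no test; the median log2 change was -0.07, the mean 0.17 and the camera direction up (adjusted p = 0.826). The median was -0.141 without S487D replicate 1, -0.0428 without S487D replicate 2 and -0.0419 without S487A replicate 3. In the list of hormone processing and granule exocytosis, Pcsk2, a proinsulin-converting protease gene, rose from 164 ± 2.9 to 325 ± 6.4 RPKM, and Cplx1, a complexin of vesicle fusion, rose from 8.61 ± 0.82 to 20.6 ± 0.97. The granule protein gene Chgb fell from 2693 ± 37 to 1217 ± 21 RPKM and Scg5 fell from 600 ± 18 to 377 ± 13.3. Cplx1 lies in the raised stretch of chromosome 14, and the Pcsk2 row overlaps another transcript. Of 29 tested, 11 rose, 9 fell and 9 passed no test, or 11 and 10 adjusted over the list alone. Their median log2 change was -0.01, their mean 0.03 and the camera direction up (adjusted p = 0.612). The median turned positive after quantile normalization (0.06) and median centring (0.05), with a filter at RPKM 5 (0.03), with the most read genes left out (0.09) and without S487A replicate 1 or 2 or S487D replicate 2 (up to 0.03). Leaving out the most read genes removes Chgb and another fallen member of this list.

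Target genes of cAMP and CREB rose more often than they fell. Crem, a cAMP-inducible regulator of CREB, rose from 2.45 ± 0.17 to 6.98 ± 0.30 RPKM and Pde10a, a cyclic nucleotide phosphodiesterase gene, from 5.31 ± 0.87 to 11.4 ± 0.34. Bdnf fell from 3.85 ± 0.25 to 0.829 ± 0.168 RPKM and the stress factor Atf3 fell from 7.41 ± 0.49 to 4.64 ± 0.64. Of 18 tested, 11 rose, 2 fell and 5 passed no test (median log2 change 0.16, or 0.107 without S487D replicate 3, camera adjusted p = 0.00415). The adjusted p = 0.574 with an estimated correlation. FoxO1 targets did not move together, with 6 of 19 rising, 9 falling and 4 passing no test (median log2 change -0.17, camera adjusted p = 0.584). Ccnd2, a cyclin of G1 phase, rose from 86.2 ± 1.2 to 147 ± 4.1 RPKM and Irs2, an adaptor of insulin signalling that is also on the cAMP list, rose 1.34-fold. Insr, the insulin receptor gene, fell from 7.02 ± 0.31 to 3.3 ± 0.14 RPKM, in a row that overlaps another transcript, and Txnip, a thioredoxin inhibitor, fell from 389 ± 23 to 253 ± 8.3.

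Menin and MLL target genes also went both ways. Among genes for inhibitors of cyclin-dependent kinases, Cdkn2c rose from 28.1 ± 0.79 to 50.4 ± 3.2 RPKM (log2 change 0.82, SE 0.053, adjusted p = 2.54e-06), Cdkn1a from 32.0 ± 1.7 to 57.7 ± 3.3, and Cdkn1b from 67.5 ± 2.0 to 81.0 ± 5.2 (log2 change 0.26, adjusted p = 0.00275). Gast and Glp1r, which this list shares with others, fell. Of 14 tested, 6 rose, 4 fell and 4 passed no test. The median log2 change was 0.03, the mean -0.20 and the camera direction up (adjusted p = 0.718). The median turned negative without a filter on low values (-0.02) and without S487D replicate 3 (-0.02), and was 0.157 without S487D replicate 2.

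Cell cycle genes rose more often than they fell. Ccnd2 and the G1/S cyclin Ccne1 rose, the latter from 42.7 ± 1.4 to 65.2 ± 0.85 RPKM, while the mitotic kinase Aurkb fell from 92.9 ± 2.9 to 65.5 ± 2.8 and Ccnd3 fell from 29.9 ± 1.0 to 20.5 ± 1.3. Of 39 tested, 21 rose, 5 fell and 13 passed no test, or 26 and 7 adjusted over the list alone (median log2 change 0.17, camera adjusted p = 3.85e-04). The adjusted p = 0.574 with an estimated correlation. Genes of ER stress and the unfolded protein response also rose more often than they fell. Sdf2l1 rose from 28.7 ± 2.3 to 54.0 ± 2.0 RPKM and Hspa5, the chaperone BiP, rose from 429 ± 8.9 to 601 ± 16. The amino acid synthesis genes Asns and Psat1 fell 1.23-fold and 1.14-fold. Of 28 tested, 16 rose, 3 fell and 9 passed no test (median log2 change 0.16, camera adjusted p = 9.47e-04). The adjusted p = 0.574 with an estimated correlation.

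Nuclear genes of oxidative phosphorylation rose more often than they fell, by small amounts, though many passed no test. Ndufb6 and Ndufa9, subunits of respiratory complex I, rose 1.31-fold and 1.27-fold. Ndufb5, another subunit, fell from 55.9 ± 1.8 to 35.3 ± 0.05 RPKM and lies in the lowered stretch of chromosome 2. Of 40 tested, 23 rose, 1 fell and 16 passed no test (median log2 change 0.20, camera adjusted p = 7.13e-06). The adjusted p = 0.574 with an estimated correlation. Of ribosomal protein genes, 24 of 35 were up, 0 down and 11 passed no test, or 26 and 0 adjusted over the list alone (median log2 change 0.19, camera adjusted p = 4.99e-08). The adjusted p = 0.574 with an estimated correlation. Rpl5 rose from 268 ± 8.0 to 463 ± 9.3 RPKM, inside the raised stretch of chromosome 14. Ribosomal protein genes have many pseudogenes, which makes their single values uncertain. The 13 protein genes encoded in mitochondria were not analysed here.

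Lipid and sugar metabolism showed mixed changes. In sterol and fatty acid synthesis, 5 of 26 genes rose, 12 fell and 9 passed no test (median log2 change -0.06, or -0.0326 without S487D replicate 2 and -0.109 without S487D replicate 3, camera adjusted p = 0.202, and 0.0312 after quantile normalization, within a range of 0.0312 to 0.618 over 18 alternatives). Sqle, squalene epoxidase, fell from 65.4 ± 3.5 to 41.5 ± 1.1 RPKM and Acaca, the carboxylase that commits carbon to fatty acids, fell 1.32-fold. Fdps rose 1.16-fold and Acly, ATP citrate lyase, rose 1.21-fold, a call lost after quantile normalization (log2 change 0.06, adjusted p = 0.279, within a range of 4.34e-10 to 0.279 over 16 alternatives). In glycolysis and the hypoxia response, 8 of 19 genes rose, 5 fell and 6 passed no test, or 10 and 6 adjusted over the list alone. The median log2 change was 0.10, or 0.0561 without S487D replicate 2 and 0.0615 without S487A replicate 1, the mean -0.00 and the camera direction up (adjusted p = 0.488). Aldoa and Pgk1 rose 1.28-fold and 1.17-fold, the former in a row that overlaps another transcript. The hypoxia-induced gene Bnip3 fell from 28.5 ± 0.53 to 16.1 ± 2.5 RPKM, and the phosphofructokinase gene Pfkm fell 1.35-fold within the lowered stretch of chromosome 7.

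Interferon response genes fell more often than they rose, though many passed no test. Oas1b, an antiviral oligoadenylate synthetase gene, fell from 15 ± 0.54 to 7.19 ± 0.34 RPKM and Usp18, which restrains interferon signalling, fell from 3.59 ± 0.31 to 0.828 ± 0.359. The immunoproteasome gene Psmb8 rose 1.21-fold. Of 24 tested, 1 rose, 12 fell and 11 passed no test (median log2 change -0.15, camera adjusted p = 0.026). The adjusted p = 0.574 with an estimated correlation and 0.0621 with voom on recovered reads, within a range of 0.0115 to 0.574 over 18 alternatives.

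Of genes that mature beta cells keep low, 3 of 8 rose, 2 fell and 3 passed no test (median log2 change 0.09, or 0.222 without S487A replicate 3, camera adjusted p = 0.647). Mgst1 and Igfbp4 rose 1.43-fold and 1.51-fold, while Oat fell 1.18-fold and Cxcl12 fell from 1.71 ± 0.21 to 0.469 ± 0.038 RPKM (log2 change -0.88, and -1.67 with a pseudocount of 0.1). Among extracellular matrix and mesenchymal markers, 3 of 9 rose, 4 fell and 2 passed no test (median log2 change -0.05, mean -0.90, camera adjusted p = 0.652). The fibronectin gene Fn1 rose from 20.3 ± 0.91 to 59.0 ± 4.2 RPKM and the surface glycoprotein gene Thy1 rose 1.5-fold. The list's median turned positive after median centring (0.01) and when any S487A library was left out, up to 0.23. Neuronal genes rose in 6 of 20 cases, fell in 7 and passed no test in 7 (median log2 change -0.13, or 0.00319 with a filter at RPKM 5, camera adjusted p = 0.718), with Nefh up 1.3-fold, Gap43 up 1.27-fold, Map2 down 1.56-fold and Ncam1 down 1.32-fold. Of 25 markers of acinar, ductal, endothelial and blood cells, 4 were tested, too few for a list test, and the highest value of any other in a library was 0.996 RPKM. Krt7 fell from 217 ± 9.5 to 82.7 ± 2.0 RPKM, within the lowered stretch of chromosome 7, and Muc1, an epithelial mucin gene, fell from 1.44 ± 0.09 to 0.530 ± 0.181. Ctrb1, an acinar chymotrypsinogen gene, rose from 0.401 ± 0.169 to 1.42 ± 0.09 RPKM.

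**Figure D2:**
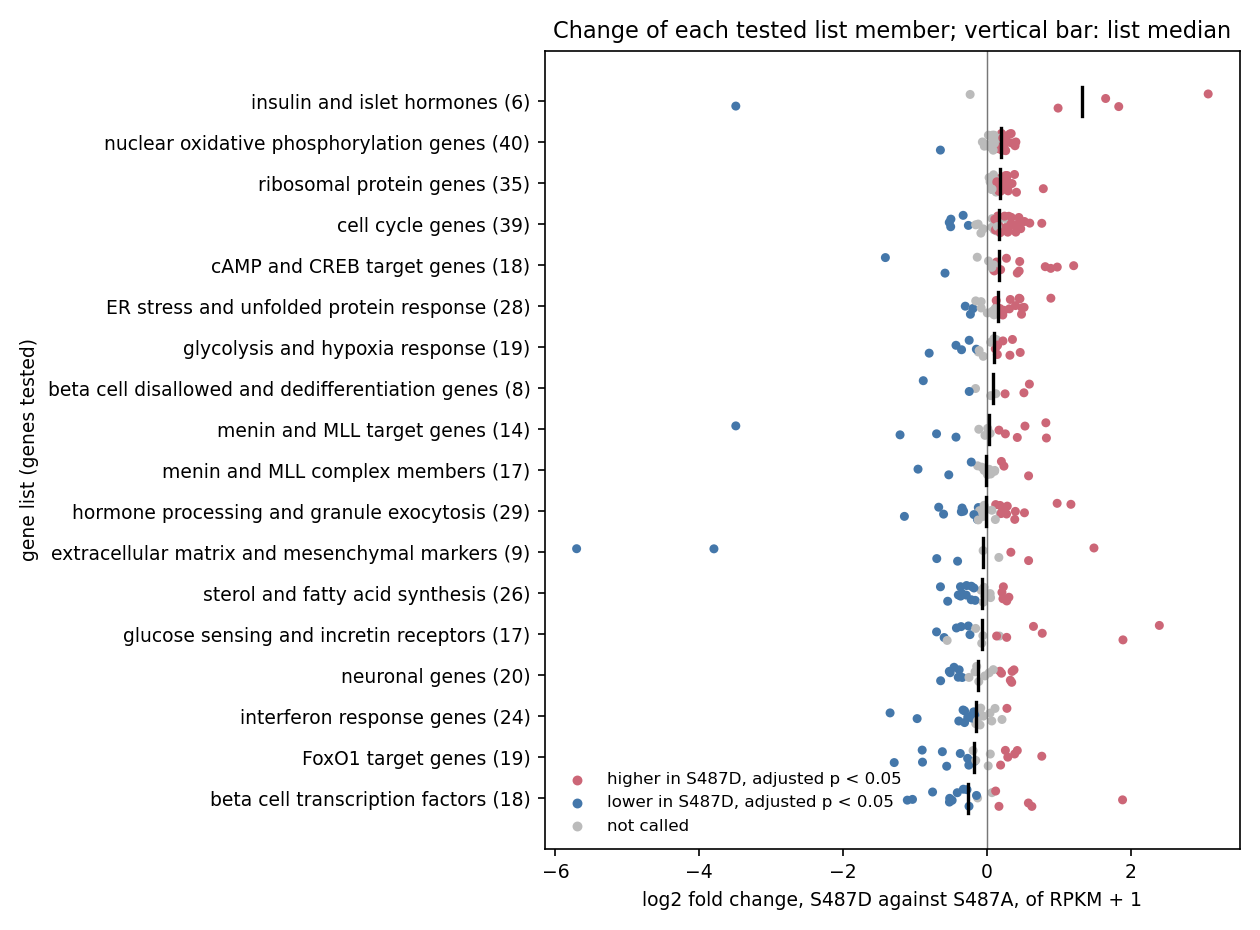
Log2 fold change (S487D against S487A, of RPKM + 1) of each tested member of 18 gene lists, coloured by its call, with the list median as a vertical bar and the number tested in brackets. Members of the oxidative phosphorylation and ribosomal protein lists sit close together near 0.20 and 0.19, while hormone genes spread from -3.49 to 3.08.

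Outside the lists, the neuropeptide gene Nts rose from 0.481 ± 0.107 to 12.9 ± 0.31 RPKM, from 4, 5 and 3 reads per S487A library to 108, 97 and 95 in S487D. Wnt4, a secreted Wnt ligand gene, rose from 5.73 ± 0.45 to 35.5 ± 3.8 RPKM, the glycoprotein hormone gene Stc1 from 8.4 ± 0.39 to 42.8 ± 3.1 and the endothelin gene Edn3 from 2.11 ± 0.68 to 13 ± 2.0. Igsf21, whose row overlaps another transcript, rose 4.08-fold and Tmem178a rose from 0.914 ± 0.330 to 5.95 ± 0.60 RPKM. Upk3bl had 0 reads in S487A and 114 in S487D, where it reached 4.0 ± 0.34 RPKM. That is at least 40.6-fold higher than the 0.0987 RPKM that 3 reads over the S487A group would give. Such floors cover counting error only. The mitochondrial glycine tRNA gene Trng was at 321, 330 and 74.7 RPKM in the S487D libraries against 37.2 to 45.4 in S487A, so S487D replicate 3 sets its size. The log2 change was 2.24 with all libraries and 2.95 without that library.

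Steep falls were seen in S100 genes that lie close together on chromosome 2. S100a6, from 190007038 to 190008512, fell from 89.3 ± 8.6 to 0.729 ± 0.102 RPKM, or from 451, 460 and 524 reads to 4, 4 and 3 (log2 change -5.70, SE 0.078, adjusted p = 1.68e-10). S100a4, from 189997278 to 189999587, fell from 3359 ± 166 to 242 ± 22 RPKM, and S100a3, from 189955630 to 189996029, from 51.8 ± 2.1 to 2.89 ± 0.11. The S100a3 row overlaps other rows. The keratin gene Krt80 fell from 63.7 ± 4.1 to 2.59 ± 0.23 RPKM and Rnd1 from 543 ± 9.0 to 59.9 ± 1.6, both in the lowered stretch of chromosome 7. Muc13, an epithelial mucin gene, fell 9.31-fold and the receptor gene Adora1 fell 7.59-fold. The receptor gene Gpr22 fell from 20.3 ± 2.5 to 1.48 ± 0.36 RPKM (log2 change -3.11, and -3.72 with a pseudocount of 0.1) and Serpina1, the alpha-1-antitrypsin gene, from 16.8 ± 1.6 to 1.18 ± 0.10 (-3.03, and -3.73). Ifi27l2b fell from 147 ± 5.7 to 13.8 ± 2.7 RPKM but has close paralogs, and Gfy fell from 13 ± 0.98 to 0.971 ± 0.285 in a row that overlaps Pth2, so both values are uncertain.

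Along the genome, 4 long stretches held genes that moved together. They were found after the values had been seen, where the running median of 21 genes, over every other tested gene, lay beyond a log2 change of 0.3 for at least 15 genes in a row. On chromosome 2, from 104916735 to 182037123, 127 of 147 tested genes fell and 1 rose (median log2 change -0.74). On chromosome 7, from 130431107 to 145230686, 118 of 145 fell and 4 rose (-0.51), and on chromosome 20, from 28815039 to 56196961, 84 of 101 fell and 1 rose (-0.47). On chromosome 14, from 1341718 to 10909579, 44 of 51 rose and 3 fell (0.68). Together the stretches held 444 tested genes, 3.54% of the total, of which 86.0% changed, against 42.9% elsewhere. Hdac2 (-0.53), Ndufb5 (-0.64), Pfkm (-0.43) and Rpl5 (0.79) changed by amounts near the median of their stretch. Krt80 (-4.17), Rnd1 (-3.16), Krt7 (-1.38), Rfx6 (-1.11), Cplx1 (1.17) and Foxo1 (-0.96) went further in the same direction, Foxo1 by the least (-0.212 from the median of its stretch). Of other listed genes, chosen after their values were seen, Nkx6-1 (-1.03) went against the raised stretch of chromosome 14, and Slc2a2 (0.28) and Nr4a1 (0.45) went against the lowered stretches of chromosomes 2 and 7. A run on chromosome 1, from 102079745 to 107373807, passed the same bound for 11 genes in a row, too few for the rule. In it 20 of 21 tested genes fell, Abcc8 (-0.42) among them, and 1 rose (median log2 change -0.45). With the 4 stretches left out, 5131 of 12083 genes changed.

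**Figure D3:**
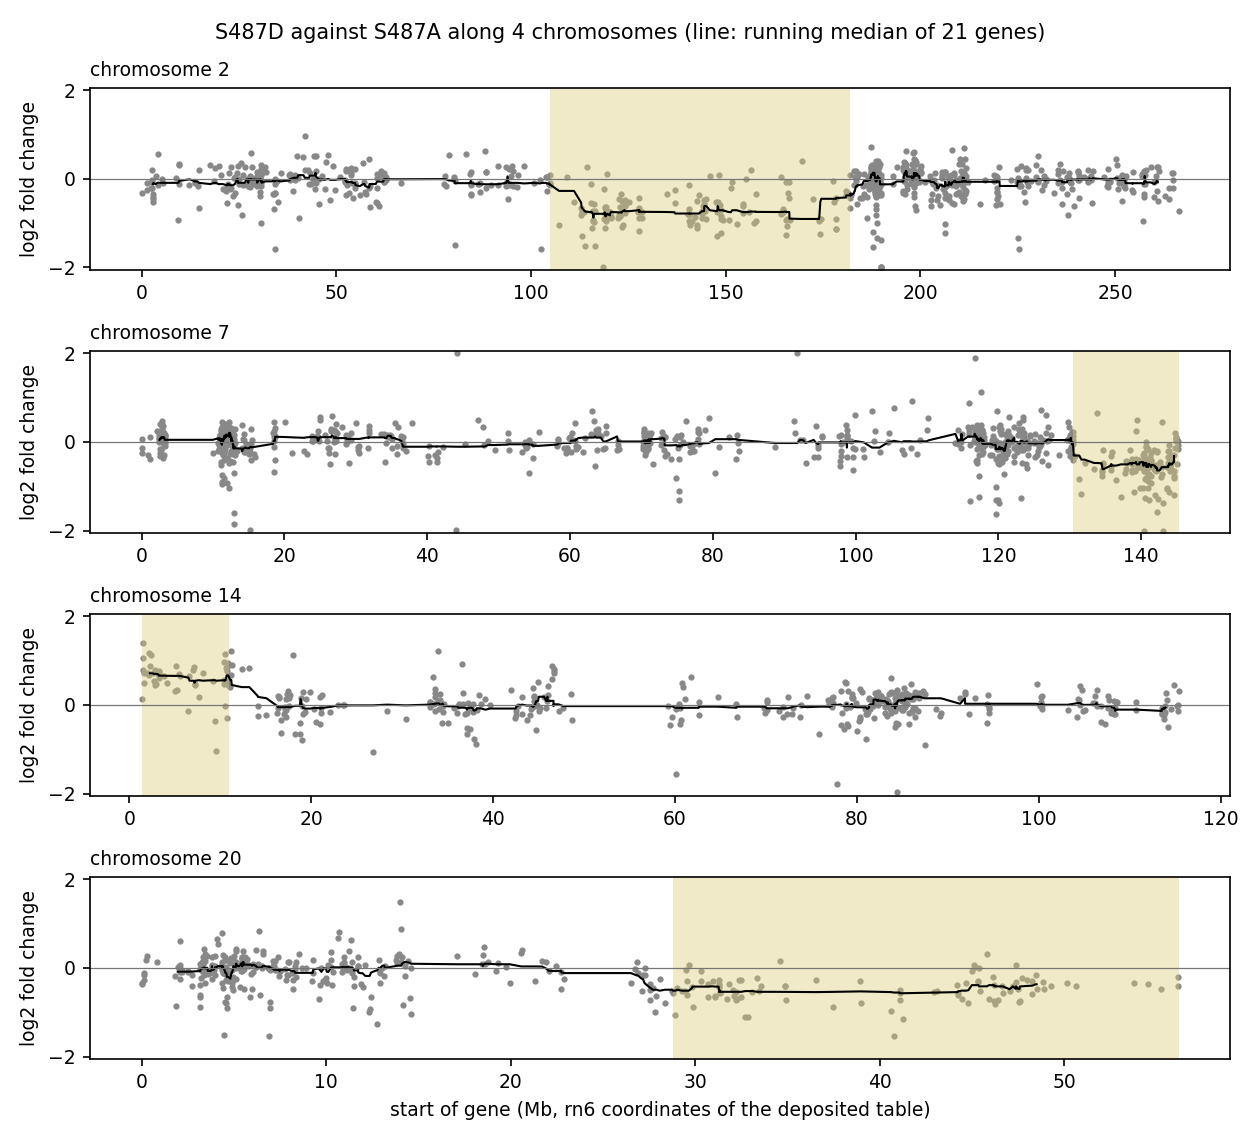
Log2 fold change of each tested gene (points, S487D against S487A) by its start on chromosomes 2, 7, 14 and 20 in Mb of rn6, with the running median of 21 genes as a line; points beyond the axis lie at its edge. Shading marks the 4 stretches, with medians of -0.74, -0.51, 0.68 and -0.47 in that order of chromosomes.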

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

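The count of changed genes stayed within 1.5 times of 5564 in each alternative tried, from 4578 with a filter at RPKM 5 to 5965 after median centring, and from 4603 to 4851 with a library left out. Voom on recovered reads, leaving out the most read genes and leaving out the shifted stretches were chosen after seeing the data, as was the test of families. The other settings were planned. The edgeR count model, planned for a table with raw counts, was not run. At 2-fold or more, 68 higher and 244 lower genes became 118 and 417 with a pseudocount of 0.1. The numbers were 126 and 441 with 0.01, and 127 and 440 with voom. A pseudocount of 1, added to RPKM, shrinks the folds of genes with low RPKM. The fold of 12 named genes moved by over 1.5 times for this reason, such as those of Nts (log2 change 3.23, and 4.50 with a pseudocount of 0.1) and S100a6 (-5.70, and -6.76). The 7 lists called with a preset correlation became 0 with an estimated correlation, which widens each list's error by its members' correlation (adjusted p = 0.574 for each; unadjusted p 0.0741 to 0.223); over the other alternatives their adjusted p ran from 1.67e-10 upward. Of 89 named genes, 88 were called, 85 of them in every alternative that tested them, up to 17; Pdx1, Acly and Ins1 were lost in some. Most were named because they were called, many with the largest changes or smallest p, so these counts do not measure the stability of calls in general. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.0035, -0.06 and 0.01 across genes, and those of other pairs from -0.0997 to 0.101. With the replicate number as a block, 5335 genes changed, 5133 of them shared with the 5564, and 7 lists were called. Values without a call crossed 0 in some settings. Some settings also drop members of a list, and the cause was not tested. The log2 fold change of Creb1 (-0.02) was 0.0951 after quantile normalization, 0.0347 after median centring and -0.056 to 0.0363 with a library left out. After median centring the median of the extracellular matrix list became 0.00709, of the granule list 0.0488 and of the menin complex list 0.0531. Quantile normalization gave 0.0569 for the granule list and 0.0397 for the menin complex list, and the filter at RPKM 5 gave 0.031 and 0.00218, with 0.00319 for neuronal genes. Leaving out the most read genes gave 0.0943 for the granule list, but it removes Chgb and another fallen member, which by itself raises that list's median. The same setting gave 0.0196 for the menin complex list, which was 0.00891 with the stretches left out. The menin target list was -0.0171 without a filter. With a library left out, medians ran from -0.0646 to 0.228 for extracellular matrix, -0.0253 to 0.0271 for granule genes, -0.0361 to 0.0242 for the menin complex and -0.0238 to 0.157 for menin targets. Depths of 9444801 to 10867549 reads per library and 3 libraries per group limit what can be seen of small changes. In simulated data 22.4% of changes of 1.2-fold were recovered, but the simulation gave 163 calls against 5564 here. Its adjusted threshold was thus stricter, and its share does not measure recovery in these data.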

Other observations

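The test of the stretches, the chromosome medians without them, the count with the most read genes left out, the families and the genes named in the next sentences were chosen only after the results were seen. Krt8 and Krt18, the paired keratins of simple epithelia, fell from 1267 ± 50 to 612 ± 5.7 RPKM and from 85.5 ± 4.9 to 40.6 ± 0.54, within 1 Mb of Krt7 and Krt80 in the lowered stretch of chromosome 7 (limma adjusted p = 9.53e-08 and 2.56e-07). C1r and C1s, adjoining genes of the first complement component on chromosome 4, fell from 11.9 ± 0.88 to 4.59 ± 0.69 RPKM and from 5.09 ± 0.65 to 1.13 ± 0.08. Mybph, next to Adora1 on chromosome 13, fell from 9.69 ± 0.22 to 0.894 ± 0.054 RPKM. Vil1, an actin-bundling protein gene of brush borders, fell from 50.7 ± 1.8 to 8.57 ± 0.41 RPKM, and Th, the rate-limiting enzyme of catecholamine synthesis, fell from 7.16 ± 0.28 to 0.449 ± 0.134.

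Families of genes with a shared symbol root were tested with camera over 69 families of at least 15 tested members. The root alone set membership, so a family such as Rps may hold genes that do not encode ribosomal proteins. Genes named Rpl rose in 25 of 45 cases and fell in 0 (adjusted p = 6.28e-06), and genes named Rps rose in 22 of 39 and fell in 5 (0.00222). Mitochondrial ribosomal protein genes followed, with 13 of 28 Mrps genes up and 2 down (0.00564) and 12 of 40 Mrpl genes up and 1 down (0.0064). No other family passed, and each of these calls was lost with an estimated correlation (adjusted p = 0.984).

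The changes were broad, with 5564 of 12527 genes called. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one, and the highest of the others gave 0; 10 splits are too few for a share under 0.05. A few genes taking many of the reads are argued against as the cause, since 5797 genes changed once the most read genes and ribosomal RNA were left out and the libraries rescaled. Copy number differences at the scale of chromosomes were left undecided. Chromosome 20, the farthest from 0, had a median log2 change of -0.1043. That is just past the bound of 0.1 set against them and short of the 0.2 set for them. Its median was -0.0107 without its lowered stretch. With all 4 stretches left out the farthest median was -0.03617 (chromosome X, 95% interval -0.0588 to -0.0109). The stretches were picked for being shifted, so medians without them cannot decide the question. Outside them 5131 of 12083 genes changed, so most calls lay outside the stretches. The stretches hold 3.54% of the tested genes, so leaving them out could not have removed most calls. Effects of the genes inside them on genes elsewhere were not tested. The mutant stays open and untested as a cause, since it goes together with the cell population that carries it, and populations may also have drifted apart in culture.

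Large changes clustered among neighbouring genes. Adjacent tested genes without overlap both changed 2-fold or more in the same direction in 27 pairs, against a median of 4 (95% range 1 to 9) in 10000 shuffled gene orders (permutation p = 1e-04, the smallest they can give), and in 20 pairs outside the shifted stretches against 3 (0 to 7, p = 1e-04). The stretches were found from every other gene. Of 220 held-out genes in them, called or not, 92.73% had a log2 change of the stretch's sign (exact binomial 95% interval 88.46 to 95.79). The interval treats genes as independent, though they lie in 4 stretches and share the same 6 libraries, so it may be too narrow. Of 1000 shuffled orders, 4 gave any stretch. Copy number differences of chromosome segments between the cell populations could give such a pattern, but DNA was not analysed here. Regulation over long domains stays open. For S100a3, S100a4 and S100a6 a lowered stretch that reaches toward lower coordinates is argued against, since the 27 other tested genes within 1 Mb, all on that side except S100a5, had a median log2 change of -0.03937 (95% interval -0.14 to 0.086), although S100a5 and Kcnn3 fell 2-fold or more; no gene on the other side was tested, so a stretch there stays open. Regulation by the mutant over short clusters such as this remains a hypothesis without a test in these data.

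Of ribosomal protein genes 24 of 35 rose slightly and 11 passed no test, and of nuclear genes of oxidative phosphorylation 23 of 40 rose, Ndufb5 fell and 16 passed no test; both list calls were lost with an estimated correlation (adjusted p = 0.574), and both lists hold mostly short and abundant transcripts. Among 10000 random lists of other genes matched on length and mean level, the ribosomal list's median log2 change (0.19, against 0.15 with a 95% range of 0.081 to 0.221) lay at percentile 81.81, so gene length and abundance may account for it. The oxidative phosphorylation list's median (0.20, against 0.11 with a 95% range of 0.048 to 0.183) lay at percentile 99.22, above that range. The random lists were drawn gene by gene and lack the correlation of the list's members (estimated at 0.2468). Their range may thus be too narrow to decide whether length and abundance account for this list. A shared effect of the mutant on these genes stays open, as does a difference in growth between the populations, which was not measured here.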
